A study of Mus musculus with 2 samples.

How the data were processed

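Innate lymphoid cells (ILCs) were sorted from colon tumours of C57BL/6 mice given azoxymethane (AOM, 10 mg/kg) and dextran sulfate sodium (DSS, 1.5%), a carcinogen and an irritant that together give colon tumours. Cells were taken at day 60 and day 120, per the labels' protocols, as cells positive for CD45 and CD127 and negative for antigens of T cells (CD3e and CD8a), B cells (CD19), erythroid cells (Ter119) and myeloid cells (F4/80, Gr1, CD11c and CD11b). Droplet-based single-cell RNA-seq libraries of transcript 3′ ends were made, 1 per time point. Per the submitters' processing notes, FastQC, Cell Ranger 2.0.1 and Seurat were used with the mm10 genome. The cell and gene filters behind the deposited table are not given in the sources used here.

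The deposited table gives 12406 genes by 1654 cells and pools both libraries. Its values are expected counts of UMIs (unique molecular identifiers), made by the authors with Cell Ranger and deposited without normalization. They are whole numbers except in 18 gene rows, where some are not (0.00626% of all values), and they were rounded to whole numbers here. Every listed gene has a UMI in at least 3 cells and the lowest cell total is 998.5 UMIs.

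Cell barcodes end in 1 of 2 suffixes, and no label or column ties a suffix to a day. The 973 cells with the first suffix are called barcode set 1 and the 681 with the second barcode set 2. No cell was therefore given to a time point, and the planned ratio of day 120 over day 60 was not computed. The same calculations were run on set 2 over set 1, whose sign says nothing about time. Each time point has 1 library, so there is no replicate and no test, and cells are not replicates. Intervals are 95% and cover counting error only: exact Poisson for CPM (a gene's UMIs scaled to the total of its class and set), exact Clopper-Pearson for shares of cells, and conditional exact binomial for ratios. A count of 0 was read as allowing up to 3 counts.

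Cells with at least 200 genes and at most 10% of UMIs from mitochondrially encoded genes were kept. This left 956 of 973 cells in set 1 and 646 of 681 in set 2. Counts were scaled to 10000 UMIs per cell and log-transformed; 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at resolution 0.8 followed (scanpy 1.11.5, leidenalg 0.10.2), over both sets together and with no correction between them. A cluster took the name of the fixed marker list, of 18, with the highest mean standardised level, with "-like" added, if at least 3 markers exceeded the other cells by over 0.5 on the log2 scale. Named classes are rebuilt here and may differ from the study's own. Doublets were kept in the main results; Scrublet, run per set as an alternative, called 3 of 956 and 5 of 646 cells.

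UMIs were summed per class and set and given as CPM. Log2 ratios had 1 CPM added. Named genes between sets were those with the 12 highest and 12 lowest ratios among genes with a mean of at least 50 CPM over all cells, and the 8 highest and 8 lowest in each class at 100 CPM and 20 UMIs, leaving out ribosomal protein, mitochondrially encoded and uncharacterised gene models. For each cluster, up to 10 leading genes by fold among genes found in at least 25% of its cells could be named. The genes of the study question were named whatever their value; they are partly known from the study itself and so are not independent of these samples. For 21 fixed gene lists, the median log2 ratio of members with at least 10 CPM was placed among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. Markers, lists, rules and most alternatives were fixed before the data were examined; the comparison of each class with the other cells of its set was added afterwards. For shares of cells with a UMI, each cell was also thinned to 1000 UMIs, which left out 1 cell.

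The ratio step was tested on simulated counts, in which 2840 genes had a mean of at least 50 CPM. Of 100 genes changed 2-fold and 100 changed 4-fold, 100% had the right direction in each case, and 95.0% and 97.0% of the intervals held the true ratio. The counts were drawn as Poisson totals per set with no variation between cells, which is the model the intervals assume. This coverage therefore checks the calculation only. It does not show that the intervals hold where a gene's UMIs come from few cells. A list of 55 raised genes lay at percentile 100, and 1 of 40 unchanged lists lay outside the middle 95% of random lists.

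Alternatives covered the cell filter, doublets, clustering resolution (0.4 and 1.5), centring of genes within each set, naming each cell on its own, the denominator, edgeR 4.0.16 TMM and DESeq2 1.42.0 median-ratio factors, a mean over cells, a pseudocount of 10 CPM and other expression minima. Positions come from the GENCODE annotation of the same mouse assembly.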

Results

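The data comprised 1654 cells sorted as tumour-infiltrating ILCs, from 2 droplet libraries, 1 from day 60 and 1 from day 120 of the AOM and DSS model. The study asked how tumour-infiltrating ILCs change state as colorectal cancer progresses. The table does not say which of its 2 barcode sets came from which day, so values of the sets are given side by side and no change with time is stated. After filtering, set 1 held 956 cells with 2080372 UMIs and a median of 2093 UMIs per cell. Set 2 held 646 cells with 1313636 UMIs and a median of 1885.5. Cells removed for a high mitochondrial share were 1.75% of set 1 (95% interval 1.02 to 2.78%) and 5.14% of set 2 (3.61 to 7.08%). There were no replicates, and all intervals cover counting error only.

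Over both sets, 46.7% of the 1602 cells were ILC2-like (44.2 to 49.2%), 22.5% ILC3-like (20.5 to 24.7%), 19.4% ILC1-like (17.5 to 21.4%) and 11.1% T cell-like (9.61 to 12.8%). A further cluster held 4 mast cell or basophil-like cells. ILC1-like cells carried Xcl1, a chemokine gene, and the killer receptor genes Klrd1 and Ncr1. ILC2-like cells carried Gata3, the transcription factor gene of type 2 lymphocytes, with the cytokine genes Il5 and Il13. ILC3-like cells carried Rorc, the transcription factor gene of type 3 lymphocytes, with Il22 and Ccr6. These genes named the classes and are not results in themselves.

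**Figure D1:**
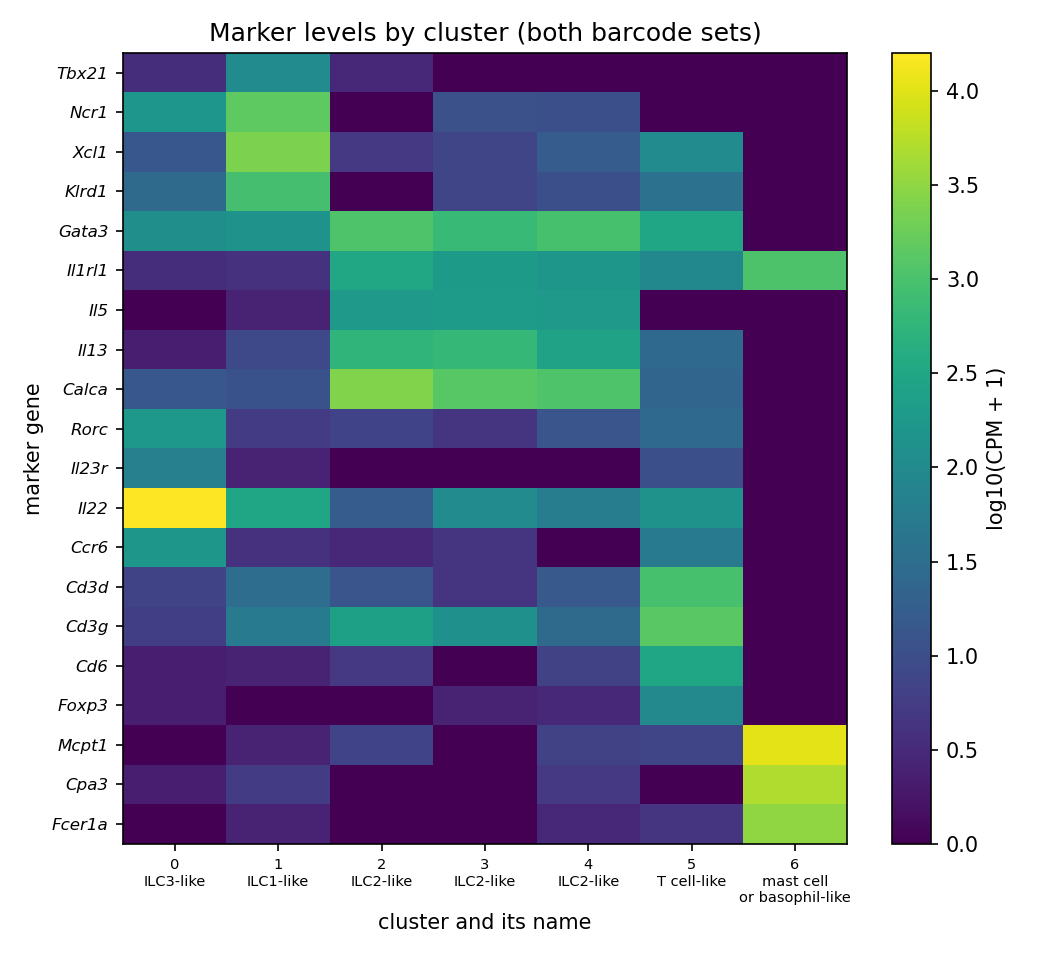
Levels of 20 marker genes (rows) in the 7 clusters (columns, with the name each took), as log10 of CPM plus 1 over both barcode sets. Il22 stood highest in cluster 0, Xcl1 in cluster 1, Cd3d in cluster 5 and Mcpt1 in cluster 6.

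The class shares differed between the sets by more than counting error. ILC3-like cells were 35.7% of set 1 (32.6 to 38.8%) and 3.10% of set 2 (1.90 to 4.74%), the latter only 20 cells. T cell-like cells were 3.66% of set 1 (2.56 to 5.06%) and 22.1% of set 2 (19.0 to 25.5%). ILC2-like cells were 37.8% (34.7 to 40.9%) and 59.9% (56.0 to 63.7%), and ILC1-like cells 22.9% (20.3 to 25.7%) and 14.2% (11.6 to 17.2%). The sort set which cells could enter these shares, and with 1 library per day a difference between sets cannot be separated from a difference between libraries.

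**Figure D2:**
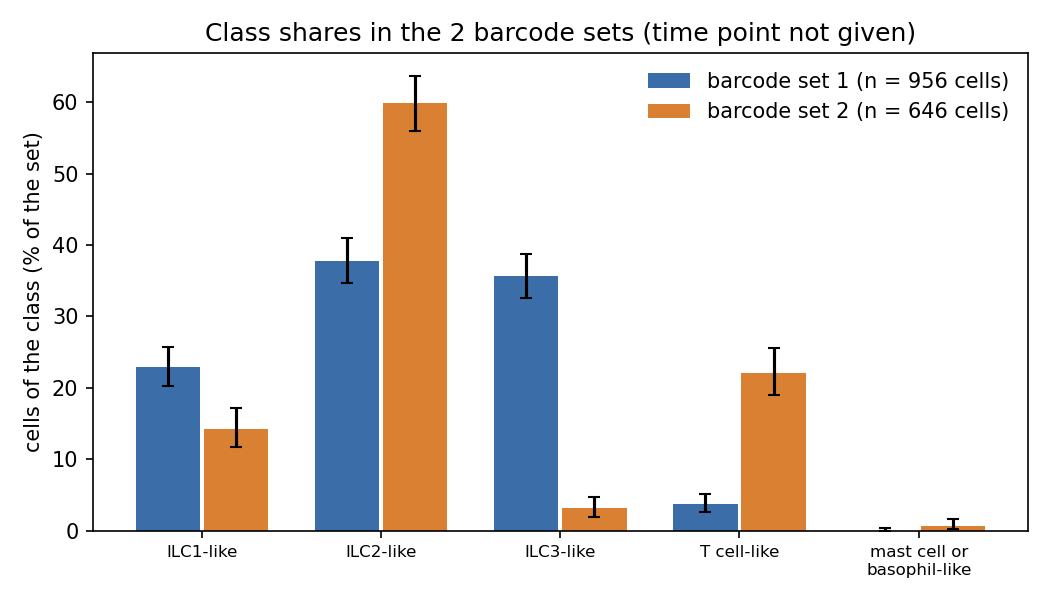
Share of each class (vertical axis, percent of the set's cells) in barcode set 1 (956 cells) and barcode set 2 (646 cells); bars are shares and whiskers exact 95% intervals. ILC3-like cells were 35.7% of set 1 and 3.10% of set 2.

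ILC2-like cells fell into 3 clusters. Cluster 2 (264 cells) was led by genes that included Calca, a neuropeptide gene, Il4, Areg, an epidermal growth factor family gene, and Il1rl1, the interleukin 33 receptor gene. Cluster 3 (263 cells) was led by genes that included Myo6, Lgmn, Il13 and Serp1. Cluster 4 (221 cells) was led by genes that included Hey1, Hs3st1, Hilpda, Fosb and Csf2. Set 2 supplied 93.6% of cluster 2 and set 1 supplied 89.7% of cluster 3, whereas cluster 4 drew 48.9% from set 1 and 51.1% from set 2. Clusters 2 and 3 each came mostly from 1 library, so their sizes are not compared.

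Among genes of the study question, Hs3st1, which encodes a heparan sulfate sulfotransferase (chromosome 5, 39613935 to 39755475, minus strand, protein-coding), was nearly restricted to ILC2-like cells. Its level in that class was 340 CPM in set 1 (302 to 382) and 882 CPM in set 2 (818 to 950). These levels were 24.9-fold (15.3 to 43.4) and 38.3-fold (21.8 to 74.5) those of the other cells of the same set. A UMI was found in 36.6% of ILC2-like cells of set 1 and 62.8% of set 2, at median depths of 2173 and 1966 UMIs. In ILC1-like cells, taken as the background, the shares were 0.913% and 3.26% at 1869 and 2255 UMIs. After thinning, the ILC2-like shares were 22.4% and 49.6%. Most ILC2-like cells of set 1 lay in cluster 3, and most of set 2 in cluster 2.

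Pdcd1, the gene of the checkpoint receptor PD-1 (chromosome 1, 94038305 to 94052553, minus strand, protein-coding), was highest in ILC3-like cells. Its level there was 466 CPM in set 1 (419 to 518) and 699 CPM in set 2 (468 to 1004), which was 5.21-fold (4.22 to 6.47) and 2.36-fold (1.56 to 3.44) the level in other cells. ILC2-like cells had 134 CPM in set 1 (110 to 161) and 371 CPM in set 2 (330 to 416). A Pdcd1 UMI was found in 19.4% and 38.5% of ILC2-like cells, and in 11.1% and 23.5% after thinning. In ILC1-like cells, at the median depths given for Hs3st1, the shares were 1.83% and 8.70%, with levels of 11.6 and 118 CPM.

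Of the remaining study genes, Gata3 reached 743 and 1048 CPM in ILC2-like cells of sets 1 and 2. Rorc reached 180 and 72.3 CPM in ILC3-like cells, the latter from 3 UMIs, and Tbx21, the type 1 transcription factor gene, 118 and 78.4 CPM in ILC1-like cells. Il7r, which encodes the CD127 used in the sort, was highest in ILC3-like cells at 918 and 940 CPM. Tgfb1 was present in each class, between 145 and 470 CPM. Of genes tied to regulatory ILCs, Il10 and Id3 were scarce: Il10 was found in 2 of 178 T cell-like cells and in 2 of 1424 other cells, and Id3 in 2.25% of T cell-like cells and 3.51% of others. The whole regulatory ILC marker list, which also holds Tgfb1, summed to 488 and 541 CPM over all cells of sets 1 and 2. With each cell named on its own, 13.7% and 9.13% of cells took the name ILCreg-like, although no cluster did. Id3 in T cell-like cells of set 1 (362 CPM) rested on 23 UMIs, 21 of them in 1 cell. Sox4 in ILC3-like cells was 18.6 CPM in set 1 and 313 CPM in set 2, where it rested on 13 UMIs in 3 cells, and on 3 UMIs (124 CPM) without the dendritic cell-like cells described below. Tgfbr1 and Tgfbr2 stayed at or below 82.2 CPM in each class and set.

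**Figure D3:**
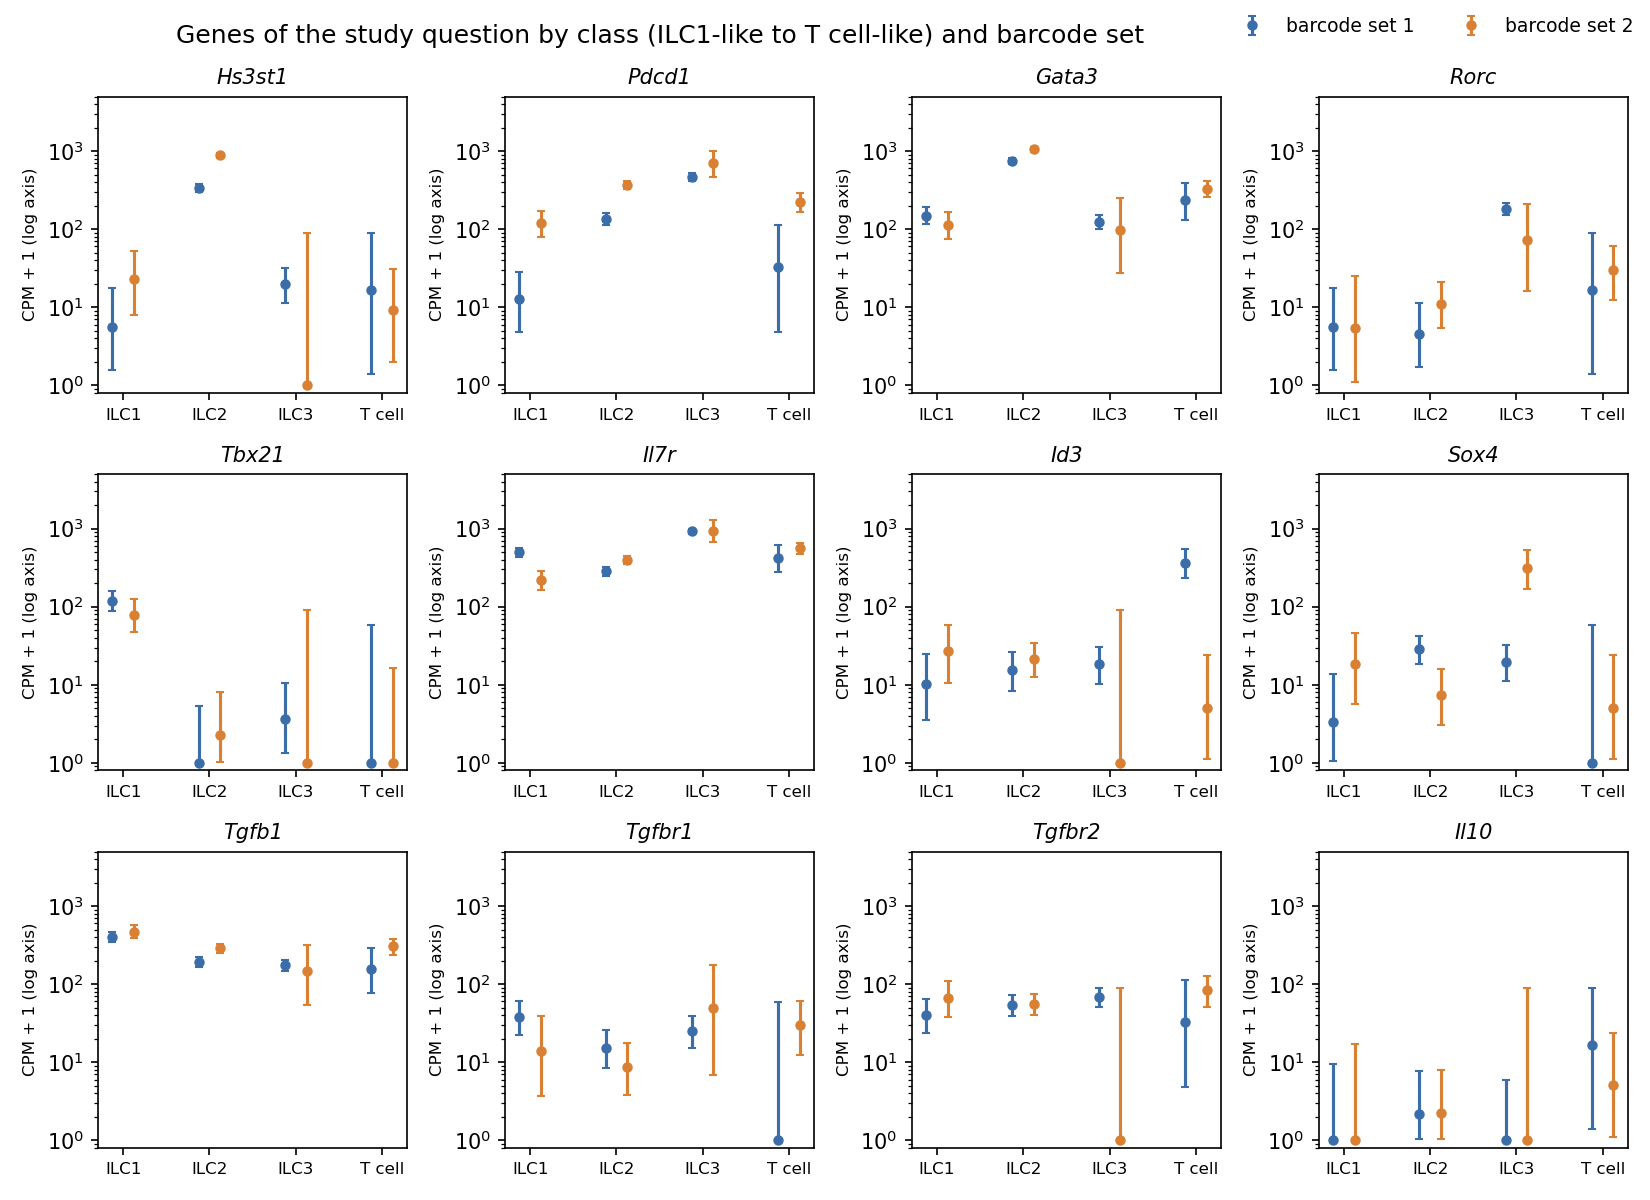
Levels of 12 genes of the study question (CPM plus 1, log axis) in 4 classes of barcode sets 1 and 2; points are summed UMIs and whiskers exact Poisson 95% intervals, so a point at 1 stands for a count of 0. Hs3st1 stood at 340 and 882 CPM in ILC2-like cells and at or below 21.8 CPM in the other classes.

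Of 21 gene lists, those above the middle 95% of random lists in both sets numbered 4 for ILC1-like, 2 for ILC2-like, 2 for ILC3-like and 2 for T cell-like cells. ILC1-like cells lay above other cells for type 1 effector genes, with medians of 4.50 and 1.66 on the log2 scale in sets 1 and 2, and for cytotoxic granule and killer receptor genes, with 4.47 and 4.20 (percentile 100 of random lists for each). In the type 1 list, 11 of 13 measured members in set 1 and 8 of 12 in set 2 were at least 2-fold higher, among them Ifng at 176 and 283 CPM against 1.82 and 3.69 CPM in other cells, and Ccl5 at 571 and 897 CPM against 24.3 and 99.6. Survival genes were also above, with medians of 0.70 and 0.64 (percentiles 99.98 and 99.62). ILC2-like cells lay above for type 2 effector genes, at 3.91 and 2.89, with 9 of 12 members at least 2-fold higher in each set, including Il13 (556 and 439 CPM against 3.21 and 19.2) and Il4 (292 and 390 CPM against 1.61 and 13.4). Several of these members are also class markers, so their direction is not independent of the naming.

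MHC class II genes, which encode proteins that present antigen to T cells, were high in part of the ILC3-like class. Clustering at resolution 1.5 split off 52 of its cells, 45 of set 1 and 7 of the 20 in set 2, which took the name dendritic cell-like from Ccr7, H2-Ab1, H2-Aa, H2-Eb1, Cd74 and Fscn1. Their next highest list was ILC3, at a mean standardised level of 0.518. The clusters named ILC3-like at that resolution had 0.569 and 0.436. Whether the 52 cells are dendritic cells or ILC3-like cells was not tested, so values without them may leave out part of the ILC3-like cells. With these cells in the class, the MHC class II median was 1.93 in set 1 and 3.28 in set 2 (percentile 100 in both). Without them it was 0.62 (percentile 95.6) and −0.84 (percentile 9.78), inside the middle 95% of random lists in both sets. Since 4 of the list's genes named these cells, that fall is in part set by the choice of cells. Cd74 was 2153 and 6534 CPM in the whole class, 1196 and 1243 CPM without the 52 cells, and 469 and 704 CPM in cells of other classes, which without them was still a ratio of 2.55 (2.29 to 2.84) and 1.76 (1.18 to 2.54). H2-Aa was 669 and 1808 CPM in the whole class, and 279 and 41.4 CPM without them, the latter from 1 UMI. Summed dendritic cell markers in the whole class were 3971 CPM in set 1 and 12826 CPM in set 2, and summed ILC3 markers 21016 and 9764 CPM. The MHC class II list lay at −2.30 and −1.60 in ILC2-like cells and at −2.47 and −1.79 in T cell-like cells, the latter class at −0.23 (percentile 14.6) in set 1 with each cell named on its own.

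Other genes raised in ILC3-like cells were Ccr7, a homing receptor gene, and the syndecan genes Sdc1 and Sdc4. Ccr7 was 423 CPM (378 to 473) and 1760 CPM (1379 to 2213) in the whole class, 236 and 994 CPM without the 52 cells, and 66.2 and 112 CPM in other cells. Sdc4 was 7.73-fold (6.53 to 9.19) and 6.93-fold (4.42 to 10.5) the level in other cells. Without the 52 cells Sdc4 was 7.37-fold (6.20 to 8.79) and 5.53-fold (2.86 to 9.80). Sdc1 was then 14.2-fold (9.01 to 23.3) and 14.4-fold (2.57 to 54.4), the latter from 3 UMIs in the class. Sdc1 is also a leading gene of the class, so its rise is not independent of the clustering. Heparan sulfate synthesis genes, the other list above random in ILC3-like cells, lay at 0.70 (percentile 97.75) and 2.91 (percentile 99.995). The list holds the syndecan genes Sdc1 and Sdc4, so it is not separate from the rise of these genes. Without the 52 cells it lay at 0.64 (percentile 95.1) and 3.08 (percentile 99.09), with 2 of 7 and 4 of 6 measured members at least 2-fold higher. Then 1 of 7 and 2 of 6 were at least 2-fold lower, and the mean log2 ratio was 0.67 and −0.088. In set 2 without these cells 1 UMI was 41.4 CPM, so members there can shift 2-fold on single UMIs. With each cell named on its own the list lay at 0.27 and 0.28 (percentiles 75.5 and 63.9). In ILC2-like cells, where Hs3st1 was highest, the list lay at −0.44 and −0.22 (percentiles 20.7 and 31.6). At resolution 1.5 the ILC3-like shares were 30.9% and 1.86%.

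Cytosolic ribosomal protein genes were higher in ILC2-like cells (medians 0.73 and 0.32) and lower in ILC3-like cells (−0.69 and −0.59), at percentile 100 and 0 of random lists. Immune checkpoint genes lay at 0.90 and 1.02 in T cell-like cells, and with each cell named on its own at 0.34 (percentile 96.0) and 0.71 (percentile 100). They were lower in ILC2-like cells (−1.16 and −1.55) and ILC3-like cells (−1.44 and −0.73; 0.17 at percentile 45.8 in set 1 with members of at least 50 CPM), although Pdcd1 itself was higher in ILC3-like cells. Naive or progenitor-like genes were lower in ILC2-like cells (−1.46 and −1.36). They lay at 0.66 and 0.53 in ILC1-like and at 0.82 and 0.57 in T cell-like cells. With each cell named on its own these were 0.64 and 0.31 (percentiles 99.7 and 89.9), and −0.24 and 0.15 (percentiles 9.70 and 74.7). Interferon response, heat shock, NF-kB target, cell cycle, MHC class I, oxidative phosphorylation, mitochondrially encoded and TGF-beta pathway lists lay outside the middle 95% of random lists in the same direction in both sets for none of the 4 classes. Type 3 effector genes in ILC3-like cells lay at 0.64 (percentile 99.87) and 0.45 (percentile 71.4). With 20 ILC3-like cells in set 2, values of that class and set are the least precise.

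**Figure D4:**
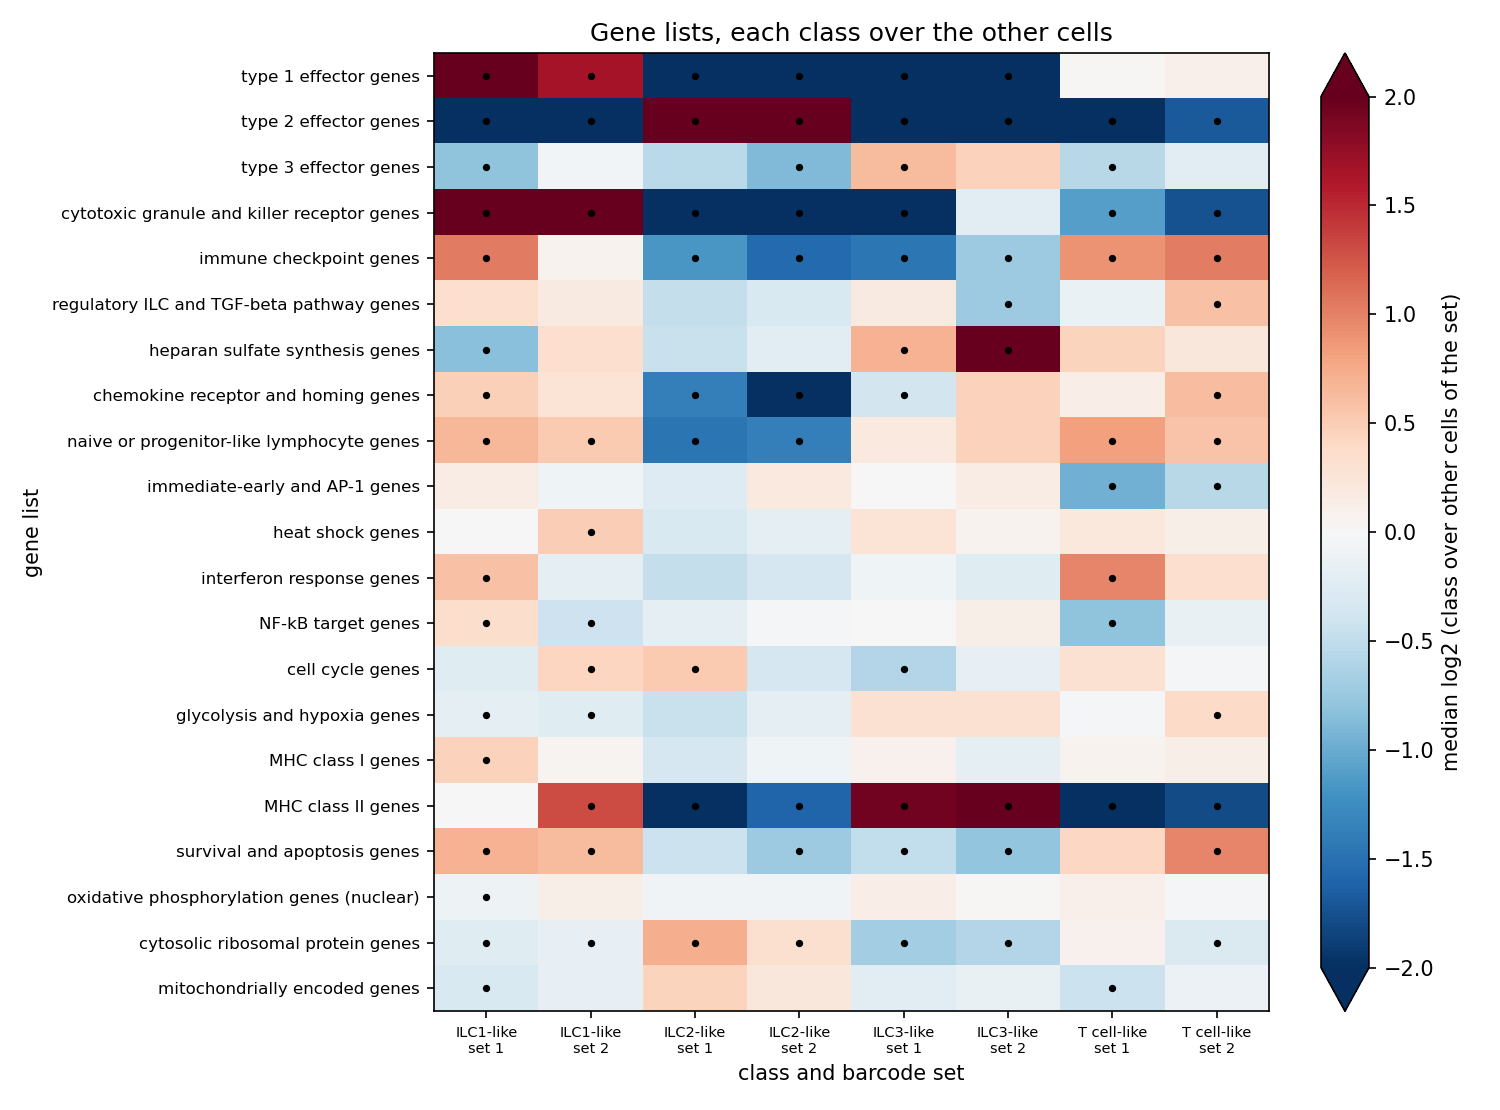
Median log2 ratio of each class over the other cells of its barcode set (colour, limited at −2 and 2) for 21 gene lists (rows) in 4 classes and 2 sets (columns); dots mark medians outside the middle 95% of random matched lists. Cytotoxic granule and killer receptor genes were at 4.47 and 4.20 in ILC1-like cells.

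T cell-like cells were present although the sort had gated out CD3e. Cd3d or Cd3g, which encode chains of the T cell receptor complex, had a UMI in 165 of 178 of them (92.7%, 87.8 to 96.1%) and in 8.92% of other cells. Tnfrsf4, the gene of the costimulatory receptor OX40, was found in 69.1% and 1.26%, and Cd6 in 34.8% and 0.351%. Foxp3, the transcription factor gene of regulatory T cells, was found in 12.9% (8.37 to 18.8%) against 0.211%, and Il17a in 14.6% (9.77 to 20.7%) against 5.13%. Cd3d, Cd3g, Cd6 and Foxp3 are markers that named the class, and Tnfrsf4 led its genes by fold. Their contrast with other cells was thus set by the naming and is not a result in itself. No cell had a Foxp3 UMI together with an Il17a or Il17f UMI. The genes Cd3e, Cd8a, Cd19, Itgam, Ly6g and Adgre1, which encode antigens of the sort panel, were not among the listed genes, and 0 T cell receptor or immunoglobulin segment genes were listed. The median depth was 1506.5 UMIs in T cell-like cells and 2066.5 in the others.

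For Il22, an epithelial repair cytokine gene, ILC1-like cells are taken as the background. In set 1 an Il22 UMI was found in 65.1% of ILC3-like, 20.1% of ILC1-like (44 of 219), 22.2% of ILC2-like (80 of 361) and 14.3% of T cell-like cells (5 of 35, 4.81 to 30.3%), at median depths of 2189, 1869, 2173 and 1513 UMIs. In set 2 the shares were 35.0% (7 of 20 cells), 2.17% (0.264 to 7.63%), 1.55% (0.571 to 3.34%) and 3.50% (1.14 to 7.97%), at 1939, 2255, 1966 and 1503 UMIs. The shares in ILC2-like and T cell-like cells lay within counting error of the background and are not read as expression there. That ILC1-like cells lack Il22 was assumed and not shown, so similar shares cannot rule out expression in any of these classes. Levels in ILC1-like and ILC2-like cells were 232 and 109 CPM in set 1. In set 2 they were 405 CPM, from 93 UMIs in 2 cells, and 12.6 CPM, from 10 UMIs in 6 cells. The background share of set 2 is thus 2 cells with many UMIs, not RNA spread evenly over the class. The Il22 level in ILC3-like cells was 16519 CPM in set 1 and 5497 CPM in set 2.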

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

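All tests in this part were chosen after the values were seen, except the clustering without Il22, whose outcome was predicted beforehand. Differences between classes in the ratio of set 2 over set 1 were not tested, since each set is 1 library of unknown day.

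Some genes moved at least 2-fold in opposite directions in different classes, with counting intervals that excluded 1 when all cells of a class were counted. Il17f, an interleukin 17 family gene, was 8.24 times as high in set 2 as in set 1 in T cell-like cells (77 of its 126 UMIs from 1 cell, and 3.24 times without it) and 0.0576 times in ILC2-like cells (128 UMIs in 26 cells against 7 UMIs in 5). Sox4 stood at 16.8 times in ILC3-like cells (10 of 13 UMIs in set 2 from 1 cell, 4.25 times without it, and 8.01 times, 1.42 to 31.1, without the dendritic cell-like cells) and 0.229 times in ILC2-like cells. Ccl1, a chemokine gene, stood at 6.06 times in ILC1-like cells (89 of 126 UMIs from 1 cell, and 1.82 times without it) and 0.236 times in ILC2-like cells (35 of 58 UMIs in set 1 from 1 cell, and 0.593 times without it). Klf2, a transcription factor gene of lymphocyte recirculation, stood at 2.06 times in T cell-like cells and 0.323 times in ILC2-like cells. Ifitm2 stood at 5.49 times in ILC2-like cells and 0.282 times in T cell-like cells, and Ifitm1 at 2.29 times in ILC2-like, 0.178 times in ILC3-like (2 UMIs in set 2, and 0 without the dendritic cell-like cells) and 0.0387 times in T cell-like cells (23 of 27 UMIs in set 1 from 1 cell, and 0.236 times without it). Rhoc stood at 2.90 times in ILC2-like, 4.83 times in ILC3-like (2.76 times, 0.539 to 8.91, without the dendritic cell-like cells) and 0.174 times in T cell-like cells (5 of 9 UMIs in set 1 from 1 cell, and 0.353 times without it), and Nmrk1 at 2.68 times in ILC1-like and 0.242 times in ILC3-like cells.

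Mast cell or basophil-like cells, which were compared as no class of their own and entered only values over all cells or over other cells, were 0.619% of set 2 (4 of 646 cells) and 0 of 956 in set 1, where a count of 0 allows up to 0.314%. They carried Mcpt1, Cpa3 and Fcer1a.

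The ILC3-like share was 11.5 times as high in set 1 as in set 2, and between 5.72 times (each cell named on its own) and 16.6 times (resolution 1.5) under the alternative settings, with 7.09 times where genes were centred within each set. A difference in depth does not account for it, since the ratio was 12.8 with every cell thinned to 1000 UMIs and clustered again. Free Il22 RNA drawing other cells into the class does not account for it either. With Il22 left out of the clustering and the markers, 4 of 1602 cells changed class, and the ratio was again 11.5. Of these cells, 1 joined and 1 left the ILC3-like class. The test covers Il22 alone, and free RNA of other genes of the class was not tested. With 1 library per time point, a difference in the sort or library preparation cannot be told apart from one between the days, and the day of each set is not given. A difference between the days remains open and untested.

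T cell-like cells made up 11.1% of the kept cells after a sort against CD3e. Doublets of a T cell and an ILC would hold more UMIs than single cells, but the median depth was 0.729 times that of other cells; Scrublet called 3 of the 178 (1.69%), a higher share than the 0.267% to 0.554% in the ILC classes. Free RNA from T cells would reach all cells alike, whereas with the T cell markers left out of the clustering, the share with a Cd3d or Cd3g UMI in the cluster where it was highest was 17.7 times that in other cells of set 1 and 6.00 times that in set 2. T cells that passed the gate and ILCs that carry Cd3 transcripts cannot be told apart, since 6 of the sort panel's genes, Cd3e among them, and the T cell receptor genes are not listed. No biological explanation was tested.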

How the results depend on the processing

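No paired analysis was possible because each time point has 1 library, and for the same reason no replicate could be left out. Thinning before clustering, leaving out stromal or dendritic cell-like cells and the settings for class against other cells were chosen after seeing the data. Among alternative values of the main results, 138 stayed within counting error or within 1.5 times the count, and 26 moved. For single genes and lists, 531 stayed, 58 moved and 9 reversed.

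ILC2-like shares of sets 1 and 2 were 25.8% and 45.8% with each cell named on its own, where 13.7% and 9.13% of cells took the name ILCreg-like, a class that clusters did not give. The same setting gave ILC3-like shares of 31.9% and 5.57% and a T cell-like share of 5.86% in set 1. With every cell thinned, the ILC2-like shares were 31.5% and 45.7%, because a cluster of 163 cells took the mast cell or basophil name. The stricter cell filter gave 31.8% ILC2-like cells in set 1. ILC3-like shares were 30.9% and 1.86% at resolution 1.5, and 4.95% in set 2 with genes centred within each set. With ILC classes alone as the denominator, set 2 held 18.4% ILC1-like and 77.6% ILC2-like cells, by construction. The order of the sets held under these settings for each class that had a share in them; T cell-like cells had none with ILC classes alone.

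Of the 24 genes named over all cells, 3 were still among the top genes with a mean CPM of at least 10, where more scarce genes compete. With each cell named on its own, 10 of 16 ILC1-like, 3 of 16 ILC3-like and 4 of 16 T cell-like genes remained, and 8 T cell-like genes stayed at least 2-fold apart in the same direction. For T cell-like cells, 10 remained with a mean over cells and 8 without 1 cell of set 1 that held 84 of the 93 fibroblast and endothelial UMIs. Without that cell Saa3 and Serping1 reversed to 2.35 and Igfbp7 to 0.32 on the log2 scale. The values of Saa3 and Serping1 then rested on 1 UMI in set 2 against 0 in set 1, fewer than the 3 counts that a 0 allows. With each cell named on its own, Saa3, Serping1 and Igfbp7 reversed to 2.23, 2.23 and 0.25. The thinned Pdcd1 difference between sets in ILC2-like cells was 12.4 percentage points against 19.1. The cause was not tested where none is given.

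In both sets, lists above random for ILC3-like cells numbered 0 without the 52 dendritic cell-like cells, which MHC class II genes helped to name, and 1 with a mean over cells, against 2, and lists below 3 with members of at least 50 CPM, against 5. Lists above for T cell-like cells numbered 0 with each cell named on its own, against 2 (checkpoint and naive or progenitor-like genes). Between sets, the type 3 list reversed to 0.0085 and the homing list to −0.13 with members of at least 50 CPM, and the cytotoxic list to 0.023 with the same class shares in both sets. There MHC class II genes moved from −0.22 to 1.22 (within ILC3-like cells, from 1.50 to 0.06 without the dendritic cell-like cells) and interferon response genes from 0.13 to −0.25, and 14 of 21 lists lay outside the middle 95% of random lists against 9. Depth limits ILC3-like values of set 2 most: 3 UMIs there are 72.3 CPM.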

Other observations

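The values here compare barcode set 2 with barcode set 1, whose days are not given, and describe 2 libraries; tests of explanations were chosen after the values were seen, except that on pseudogenes. Over all cells, the genes with the highest ratios were Gzma, a granzyme gene (11.4-fold, 7.67 to 17.6), Penk (9.91-fold), Tnfrsf4 (9.64-fold), Gzmb (6.48-fold), Cd2 (6.25-fold), Apoe (6.02-fold), Gzmc (5.77-fold), Cd3d (5.72-fold), Cxcl2 (5.37-fold), Jchain (5.16-fold), Hey1 (4.95-fold) and Lyz2 (4.79-fold). Tnfrsf4, Cd2 and Cd3d are leading genes of the T cell-like class, which had the larger share in set 2. Jchain rested on 1 cell for 59.2% of its set 2 UMIs and was 2.12-fold without it. Gzma, Gzmb and Gzmc had 29.2%, 29.6% and 24.4% of their set 2 UMIs in 1 cell each. Without that cell they were 8.12-fold, 4.57-fold and 4.37-fold. Gzma had a UMI in 9 cells of set 1 and 22 of set 2, and Gzmc in 27 and 22. Genes higher in set 1 were Mptx1 (292 UMIs against 1, 184-fold, 32.8 to 7307), Il22 (21.6-fold, 19.5 to 24.1), Prr29, Ncoa7, Sdc1, Chad, Kcnk1, Rgcc, Serpinb1a, Igfbp7, Scn1b and Ecm1, the last 10 between 7.96-fold and 4.14-fold. Il22, Ncoa7, Prr29, Kcnk1, Chad, Sdc1 and Ecm1 are leading genes of the ILC3-like class, which had the larger share in set 1.

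Within ILC2-like cells (361 and 387 cells; mostly cluster 3 in set 1 and cluster 2 in set 2), set 2 had more Gzmb (372 against 32.3 CPM) and Gzma (227 against 20.4 CPM), found in 32 and 15 of its cells. Without the cell holding most UMIs, the Gzmb ratio was 7.30 rather than 11.5. Bcl2a1d, a survival gene (6.04-fold), Ifitm2 (5.49-fold), Lilr4b (5.49-fold), Hey1 (5.47-fold) and the chemokine gene Cxcl2 (4.78-fold) were also higher. Hs3st1 was 2.59-fold higher in set 2 (2.25 to 2.99), Pdcd1 2.76-fold (2.22 to 3.47), Ctla4 4.93-fold (2.98 to 8.58) and Areg 1.93-fold (1.72 to 2.16). The immune checkpoint list had a median of 1.17 (percentile 100), with 7 of 12 members at least 2-fold higher in set 2 and 0 lower. This was not particular to ILC2-like cells: the list lay at 1.18 (percentile 99.7) in ILC3-like and 0.80 (percentile 99.99) in T cell-like cells. In ILC1-like cells it lay at 0.16 (percentile 77.1). Summed T cell markers in ILC2-like cells were 250 and 360 CPM in sets 1 and 2. Background from T cell-like cells, more numerous in set 2, was not removed from the list. Type 3 effector genes lay at −0.80 (percentile 0): Il17f was 153 CPM in set 1 and 8.83 in set 2, and Il17a 298 and 156, against 4.64 CPM or less for each in ILC1-like cells. The list also holds Il22 (109 and 12.6 CPM), whose share in ILC2-like cells lay within counting error of the assumed ILC1-like background. Background from ILC3-like cells, more numerous in set 1, was not removed from the list. Type 2 effector genes lay at 0.42 (percentile 99.66), while Il5 was 200 and 189 CPM and Il13, with levels given above, was lower in set 2. Klf2, Cd28, Lgals3, Itga4 and Maf were higher in set 1, between 3.09-fold and 2.15-fold.

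In ILC1-like cells (219 and 92 cells), cell cycle genes had a median of 0.93 (percentile 100), with 8 of 17 members at least 2-fold higher in set 2, and heat shock genes 0.64 (percentile 99.98). Heat shock genes were also higher in set 2 in ILC2-like cells (0.56, percentile 99.8), and cell cycle genes in ILC3-like cells (0.88, percentile 99.69). Without the dendritic cell-like cells the latter value was 0.27 (percentile 76.2). In ILC1-like cells Gzmc was 8.74-fold (5.82 to 13.5) and Hspa1a 7.98-fold (4.19 to 16.4) higher in set 2. They had a UMI in 14 and 7 of the 92 cells of set 2. Without the cell holding most UMIs of each gene, the ratios were 6.23 and 5.53. Serpinb1a was 387 CPM in set 1 and 17.4 in set 2, and Hopx 218 and 34.8. Summed markers of other cell types also differed between sets 1 and 2 in ILC1-like cells. They were 1591 and 3247 CPM for dendritic cells, 39.4 and 183 for neutrophils and 78.9 and 383 for NK cells. Epithelial cell markers went the other way, with 643 and 326 CPM. In ILC3-like cells (341 and 20 cells), H2-Eb1 was 5.53-fold higher in set 2 (4.06 to 7.44), 3.19-fold without 1 cell that held 45.8% of its UMIs there, and 1.05-fold (0.124 to 3.98) without the dendritic cell-like cells, which were 45 of 341 and 7 of 20 and were named in part by this gene. Tsc22d1 (28.4-fold) was 8.35-fold and Gzmc (21.1-fold) 6.33-fold without 1 cell each, and Lgals3 was 752 CPM in set 1 and 24.1 in set 2, the latter from 1 UMI. In T cell-like cells (35 and 143 cells), Bmyc, Lilrb4a, Rnaset2b, Rheb, Pdcd1 and Ier3ip1 were higher in set 2, each from 1 or 2 UMIs in set 1. Sparc, Col18a1, Saa3, Serping1, Igfbp7 and Rgs5 were higher in set 1, with between 92.3% and 100% of their UMIs from 1 cell.

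Over all cells, 9 of 21 lists lay outside the middle 95% of random lists, among them immune checkpoint (0.80), type 2 (0.76), cell cycle (0.55) and type 3 effector genes (−0.72, but 0.0085 with members of at least 50 CPM). With the same class shares in both sets, checkpoint genes lay at 0.78, type 2 genes at 0.26 and type 3 genes at −0.46. MHC class II genes then lay at 1.22 (percentile 100; 4 of 6 members at least 2-fold higher in set 2) rather than −0.22 (percentile 6.20), and interferon response genes at −0.25 (percentile 1.73) rather than 0.13 (percentile 90.6); in this setting the 20 ILC3-like cells of set 2 carry the mean ILC3-like share of the sets. Within ILC3-like cells the MHC class II median was 1.50 (percentile 100), and 0.06 (percentile 41.2) without the dendritic cell-like cells, which genes of the list helped to name. TMM shifted all genes by −0.33 in ILC3-like and 0.17 in T cell-like cells on the log2 scale. Summed marker lists of sets 1 and 2 gave 335 and 756 CPM for macrophages or monocytes, 49.5 and 204 for neutrophils, 259 and 866 for plasma cells (234 and 363 without the cell of each set that held most), and 643 and 349 for epithelial cells. Apoe was 40.9 and 246 CPM, and was also a leading gene of cluster 2, and Lyz2 was 18.7 and 89.8 CPM.

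In each of the 4 classes, Apoe, Lyz2, S100a8 and S100a9, which macrophages or neutrophils express, were higher in set 2, and Mptx1 was higher in set 1. Free RNA from other cell types is a candidate explanation: within the set where each gene was higher, the median gene's highest class level was 1.85 times its lowest, and Mptx1 ranged from 133 to 158 CPM over the classes of set 1. The sort gated out CD11b and F4/80, which many such cells carry. Gm10260 (975 and 12.9 CPM over all cells), Gm10709, Gm8797, Gm8730, H2-T23 and Lypd8 were lower in set 2 in each class. Reads shared with near-identical copies and given to other genes in one library may account for Gm10709 and Gm8730, which are pseudogenes: the 29 pseudogene-type genes lay −0.27 from protein-coding genes of the same level, at percentile 0.03 of matched lists but between the bounds set beforehand, so this cannot be told apart from a difference between the samples, and the other 4 genes, annotated as protein-coding, were not covered.

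Eif2s3y, a Y-linked gene chosen after its values were seen, was 128 CPM in set 1 and 38.8 in set 2, while Ddx3y, also Y-linked, was 139 and 104. The Y-linked genes Uty and Kdm5d also differed less than Eif2s3y, with 22.1 and 19.0 CPM and with 19.2 and 12.2 CPM.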
